A study of Drosophila melanogaster with 7 samples.

How the data were processed

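Chromatin of wing imaginal discs was immunoprecipitated with 2 µg of antibody per the labels' protocols, and the libraries were made for Illumina sequencing. The 7 libraries were assigned to ASH2, H3K4me3, H3K27me3, H3K36me3, Ser2P, Ser5P and input DNA by the antibody each label names. For ASH2 the label also gives a catalogue number that is sold against the HA epitope tag, and the labels mention no tagged line, so what that antibody bound is taken from the label alone. Each target had 1 library, so no replicates could be compared. The input library entered no comparison and was not analysed here.

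The authors deposited 1 peak list per target, called per library, with 3 columns for chromosome, start and end. Coordinates follow dm3 per the submitters' processing notes, and starts were raised by 1 bp so that printed positions count from 1. The lists give no height, fold enrichment or p value for a peak. The aligner, the peak caller, its threshold and the use of the input as its control are not given in the sources used here. All 6 lists held entries on 2L, 2R, 3L, 3R and X. Some entries had the same start and end (306 in the ASH2 list and 108 in the H3K27me3 list), and these were kept, counted as 1 bp in overlaps and as a width of 0 bp in widths. Within a list no peaks overlapped. The entries are not in order of position, and what their order stands for is not given.

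Because the lists hold no reads, the depth of each library is unknown, and a longer list need not reflect a more abundant target. A caller's threshold sets how many weak or narrow peaks enter a list, and it also sets how a broad region is broken into pieces, so peak counts and widths of different targets are not on a common scale. Overlap shares of a pair of lists were therefore set against the same lists after shifting, whereas comparisons of peaks within or between lists by Fisher's exact test, and shares by width or by place in a list, have no shifted value unless one is printed. A peak width of 324 bp was the commonest in the ASH2 list (544 peaks) and the H3K27me3 list (340 peaks), and its origin is not given.

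Peaks of a pair of lists were called shared when they overlapped by at least 1 bp. For each of the 30 ordered pairs of lists, the share of peaks with a partner was computed with an exact (Clopper-Pearson) 95% interval, which covers the counting of peaks only. The share was compared with 10000 circular shifts of the whole list within each chromosome, which keep widths and spacing. No table of dm3 chromosome lengths was used, so a chromosome was taken to end at the last peak end of any list. Empirical p values were two-sided, with Benjamini-Hochberg adjustment over the 30 pairs and a threshold of 0.05, and 0.0002 was the smallest p possible. Alternatives and distances used 1000 shifts, with a smallest p of 0.001998. ASH2 peaks were grouped by the other 5 lists in the same way. H3K27me3 peaks were joined into domains over gaps of up to 5000 bp, and a peak was in a domain if it overlapped it. Peak width stood in for the missing peak score, as fixed beforehand, and the medians of ASH2 width with and without each mark were compared with 100000 label permutations, two-sided, adjusted over 5 marks, and with 1000 shifts. Ser5P and Ser2P peaks were compared with Fisher's exact test, two-sided, adjusted over 4 marks, with a Wald 95% interval for the difference. Densities on the X were divided by the mean of the 4 autosomal arms, with the SD over those arms. Arms are parts of 1 library and not replicates, and neighbouring peaks are not independent, so Fisher and label permutation p values are too small for regions as units.

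Named positions followed a rule set before the data were examined: the 5 widest peaks of each list, the 5 longest H3K27me3 domains and the 5 longest regions shared by ASH2, H3K4me3 and Ser5P, of which the report prints those that illustrate a comparison. Planned counts of peaks at promoters, of genes with each mark and of marks at fixed gene lists were not made, because the gene table at hand follows a later genome release than dm3 and builds were not mixed. For the same reason no genes are named.

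Other settings fixed beforehand were an overlap of at least 50% of the peak, a distance of up to 500 bp, the wider 50% of each list, the 3732 widest peaks of each list, each peak placed at random within its chromosome, peaks within 200 bp joined, domain gaps of 1000 and 10000 bp, and covered length in place of density. Added after seeing the data were shifts of 20 to 100 kb, the first 50% of each chromosome's entries, peaks of at least 100 bp, the place of an entry in its list in place of its width, polymerase peaks of 500 to 1500 bp, the first 140 H3K27me3 entries per Mb of each arm, and the 3732 widest peaks of either the ASH2 or the H3K27me3 list alone. The narrowest 30% of ASH2 peaks were also set against 1000 placements of the same widths at random, off the other ASH2 peaks. The overlap and width tests were tested on simulated data. Of 40 simulated lists of 1000 peaks placed at random against the H3K4me3 list, 5% were called with no planted overlap and 100% with 5% of peaks planted, and the mean recovered share was 5.19%. With 20% planted it was 20.0%. These simulated peaks had a single width and were placed independently, with 200 shifts per list, whereas peaks in the data vary in width and can cluster. The 5% is therefore not the rate of false calls of the overlap test in these lists. The width test called 2.5% of 40 simulations without a difference and 100% with a difference of 50 bp. Its simulated labels were drawn independently of width, whereas in the data wide peaks meet more partners. The simulation therefore does not give the rate of false calls of the label permutations in these lists. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.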

Results

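Wing imaginal discs, the larval epithelial sacs that form the adult wing, were taken from Drosophila larvae of the third instar and studied by chromatin immunoprecipitation followed by sequencing (ChIP-seq). The 7 libraries comprised 1 for each of 6 targets and 1 of input DNA. The targets were ASH2, a trithorax group protein and a subunit of the complexes that methylate histone H3 at lysine 4, then H3K4me3, the mark of active promoters, H3K36me3, the mark of transcribed gene bodies, and H3K27me3, the mark laid down by the Polycomb group. The other targets were RNA polymerase II phosphorylated in its C-terminal repeat at serine 5 (Ser5P), the form typical of promoters, or at serine 2 (Ser2P), the elongating form. The authors deposited 1 list of peak positions (dm3) per target, and the input library was not analysed here. The ASH2 library is called so after its label, although the catalogue number given for its antibody is one sold against the HA epitope tag and no tagged line is mentioned, so every ASH2 value rests on that label. With 1 library per target there were no replicates, so the tests below compare these lists, and the range over the 5 chromosome arms is given as the spread within a list.

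ASH2 and H3K27me3 gave many narrow peaks, and the active marks gave fewer, wider ones. The ASH2 list held 31582 peaks with a median width of 237 bp (interquartile range 77 to 421), and 29.2% of them were under 100 bp. The H3K27me3 list held 22620 peaks with a median of 337 bp (183 to 620) and the widest peak of all lists, at 17037 bp. H3K4me3 had 5868 peaks (median 844 bp, 623 to 1074) and H3K36me3 had 5760 (median 1257 bp, 785 to 1956). Ser2P had 4828 peaks (median 849 bp, 549 to 1328) and Ser5P had 3732 (median 692 bp, 470 to 1111). H3K27me3 peaks covered 11.8 Mb or 9.89% of the 119 Mb spanned by the lists, ASH2 peaks 8.49%, H3K36me3 peaks 7.41%, H3K4me3 peaks 4.34%, Ser2P peaks 4.27% and Ser5P peaks 2.82%. The lists hold no read counts, so the sequencing depth behind each is unknown, and a region outside a list is not thereby shown to lack the mark.

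The first comparison asked which marks and polymerase forms occupied the same regions. H3K4me3, H3K36me3, Ser2P and Ser5P overlapped each other, and each of them overlapped H3K27me3 less often than shifted peaks did. The highest ratio was that of Ser5P with H3K4me3: 57.9% of Ser5P peaks overlapped an H3K4me3 peak (95% exact interval 56.3 to 59.4, arms 56.0 to 59.9), against 7.90% when the peaks were shifted along their chromosomes, a ratio of 7.32. Of the Ser2P peaks, 50.4% overlapped H3K36me3 (arms 49.2 to 51.9; shifted 11.3%, ratio 4.45), and 38.5% of H3K36me3 peaks overlapped Ser2P (shifted 9.35%). H3K4me3 and H3K36me3 shared 45.8% of the H3K4me3 peaks (shifted 10.8%) and 45.8% of the H3K36me3 peaks (shifted 9.85%). Of the 30 ordered pairs of lists, 22 overlapped more often than shifted peaks and 8 less often. Those 8 were H3K27me3 paired with each of the 4 active marks, in both directions. For all 30 pairs the adjusted p was 0.0002, the smallest that 10000 two-sided shifts can give.

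**Figure D1:**
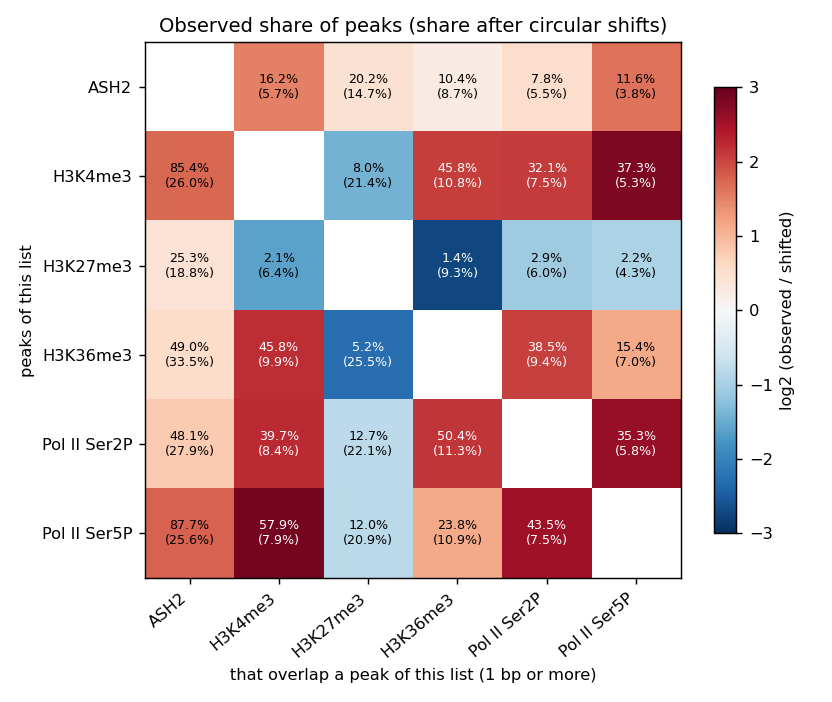
Share of the peaks of each list (vertical axis) that overlapped a peak of another list (horizontal axis) by 1 bp or more, with the share after circular shifts in parentheses and the colour giving the log2 ratio of the observed to the shifted share. H3K27me3 with each of the 4 active marks is blue, at 1.42% against 9.35% for H3K36me3, and every other pair is red.

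Ser5P peaks lay closest to H3K4me3 peaks and H3K27me3 peaks farthest from them. The midpoint of a Ser5P peak lay a median of 448 bp from the nearest H3K4me3 midpoint, that of an H3K36me3 peak 1299 bp and that of a Ser2P peak 1700 bp. ASH2 peaks lay a median of 7886 bp away. Shifted lists gave medians of 14814 to 15352 bp. H3K27me3 peaks lay farther from H3K4me3 than shifted peaks, at 18831 against 15352 bp. All of these differed from the shifts, used as a permutation test, at p = 0.001998, the smallest that 1000 two-sided shifts can give.

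A second comparison described the chromatin around ASH2. In the lists as deposited, ASH2 was present at most H3K4me3 and Ser5P peaks: 85.4% of H3K4me3 peaks (95% exact interval 84.5 to 86.3, arms 84.1 to 86.7) and 87.7% of Ser5P peaks (86.6 to 88.7, arms 85.9 to 90.1) overlapped an ASH2 peak, against 26.0% and 25.6% after shifts. With each list cut to its 3732 widest peaks, which leaves far fewer ASH2 peaks to meet, the shares were 48.4% (shifted 6.5%) and 48.1% (shifted 5.9%). In the lists as deposited, fewer H3K36me3 peaks (49.0%, shifted 33.5%) and Ser2P peaks (48.1%, shifted 27.9%) overlapped an ASH2 peak. Among H3K4me3 peaks, ASH2 was present at 94.2% of the 2187 that also held Ser5P and at 80.3% of those without it (odds ratio 3.99, two-sided Fisher's exact p = 3.529e-54). Of the 5868 H3K4me3 peaks, 2060 held both ASH2 and Ser5P, 2954 held ASH2 without Ser5P, 127 held Ser5P without ASH2 and 727 held neither. H3K4me3 peaks with and without ASH2 had almost the same median width, 844 and 843 bp.

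ASH2, H3K4me3 and Ser5P overlapped together in 2247 regions with a median length of 427 bp. The longest of these, on 3R from 7047730 to 7049873 (2144 bp), was also covered over 90.4% of its length by H3K36me3 and over 80.2% by Ser2P. The next, on 3L from 831182 to 833126 (1945 bp), and on 2R from 7780786 to 7782708 (1923 bp), were covered by H3K36me3 over 97.4% and 92.2%. The fourth and the fifth, on 3R from 11157803 to 11159718 and on 2L from 8041154 to 8042885, were likewise under H3K36me3 (83.4% and 93.4%) and Ser2P (96.6% and 89.8%). In all, 539 regions held the 5 targets other than H3K27me3, and 34 regions held all 6 targets. No gene is named for these positions because no annotation of this build was used here.

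Seen from the ASH2 side, many peaks lay outside the other lists. Of the 31582 ASH2 peaks, 17929 overlapped no other list (56.8%, 95% exact interval 56.2 to 57.3), fewer than the 71.9% of shifted peaks, and 42.6% had no peak of another list within 500 bp. An active mark without H3K27me3 was present at 23.0% (shifted 13.4%, ratio 1.71), H3K27me3 without an active mark at 18.1% (shifted 13.8%, ratio 1.31) and both at 2.17% (shifted 0.895%, ratio 2.42). H3K4me3 together with Ser5P was found at 6.84% of ASH2 peaks (shifted 2.01%, ratio 3.40). These 5 groups differed from the shifts with an adjusted p of 0.0002. By single mark, 16.2% of ASH2 peaks overlapped H3K4me3 (ratio 2.84), 11.6% Ser5P (3.08), 7.82% Ser2P (1.43) and 10.4% H3K36me3 (1.19). The excess at H3K36me3 turned into a deficit among the first 50% of each list's entries (4.97% against 5.90% shifted), and it was lost when 50% of the ASH2 peak had to be covered (7.37% against 7.44%).

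ASH2 peaks at active marks were wider than the rest. Those at Ser5P had a median width of 644 bp against 202.5 bp for those without it, and those at H3K4me3 610 against 190 bp. The differences of 441.5 and 420 bp compare with 69.7 and 65.8 bp for shifted lists, in which wide peaks also meet more partners. At Ser2P the medians were 567 and 217 bp, and at H3K36me3 425 and 219 bp. ASH2 peaks at H3K27me3 had a median of 257 bp against 232 bp, a difference of 25 bp that fell short of the 91.3 bp of shifted lists and changed sign when 50% of the peak had to be covered (-29 bp). Label permutations gave p = 1e-05 for each of the 5 marks, the smallest that 100000 can give. They make no allowance for wide peaks meeting more partners, so they cannot decide whether a mark goes with wider ASH2 peaks. The shifts, used as a permutation test, make that allowance and gave a permutation p = 0.001998 for each of the 5 marks. By the shifts, the width difference was larger than in shifted lists at each active mark and smaller at H3K27me3. The share of ASH2 peaks with H3K4me3 rose from 2.94% in the narrowest 10% of the list to 61.3% in the widest (741 to 3668 bp), and that with Ser5P from 1.99 to 47.9%. Against circular shifts, the narrowest 30% met H3K4me3 at 0.632 and Ser5P at 0.659 times the shifted share. They nevertheless met H3K4me3 1.21 times and Ser5P 1.33 times as often as peaks of the same widths placed at random off the other ASH2 peaks. Against those random places the ratio was 0.784 for H3K36me3, 0.490 for Ser2P and 1.729 for H3K27me3. The share with H3K27me3 went from 15.8% to a maximum of 24.6% among peaks of 237 to 310 bp and was 16.3% in the widest. The widest ASH2 peak, on 2L from 16350706 to 16354373 (3668 bp), was covered over 57.5% by H3K4me3 and over 18.4% by Ser5P, with no H3K27me3. The second, on 2R from 7779345 to 7782928 (3584 bp), was covered over 74.7% by H3K4me3 and over 91.9% by Ser5P. The third, on 2R from 19758275 to 19761726 (3452 bp), held no polymerase peak and was covered over 10.3% by H3K4me3.

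**Figure D2:**
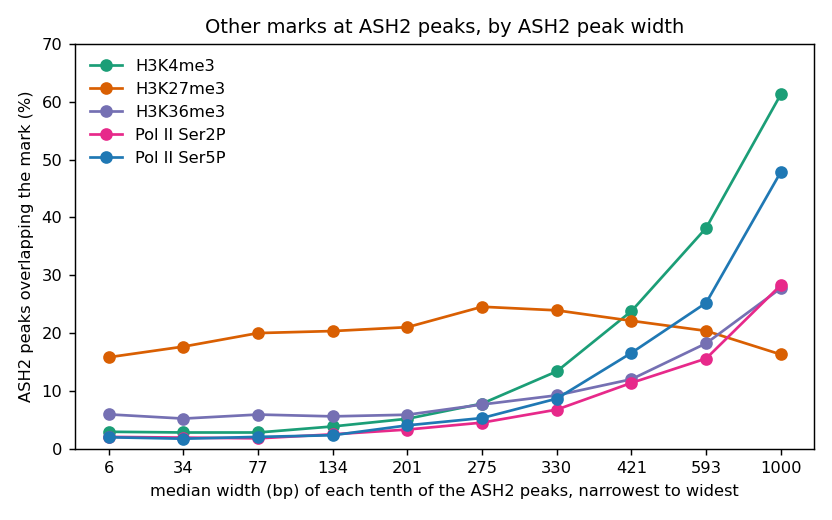
Percentage of ASH2 peaks that overlapped each other mark (vertical axis) for 10 equal parts of the ASH2 list ordered by width, labelled on the horizontal axis with their median width in bp. The lines for H3K4me3 and Ser5P climb to 61.3 and 47.9% in the widest part, and the H3K27me3 line stays between 15.8 and 24.6%.

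Another comparison set the repressive mark H3K27me3 against the active marks and ASH2. H3K36me3 showed the strongest deficit: 1.42% of H3K27me3 peaks overlapped it (321 of 22620; 95% exact interval 1.27 to 1.58), against 9.35% after shifts. H3K4me3 was found at 2.11% of H3K27me3 peaks (shifted 6.43%), Ser5P at 2.19% (shifted 4.26%) and Ser2P at 2.87% (shifted 6.02%). ASH2 went the other way, at 25.3% of H3K27me3 peaks (24.8 to 25.9, shifted 18.8%, ratio 1.35). By length, 12.97% of the ASH2 peak sequence lay inside H3K27me3 peaks, compared with 1.11% for H3K36me3, 3.99% for H3K4me3, 6.77% for Ser2P and 7.33% for Ser5P, and with 9.89% for independent placement.

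The overlap with H3K36me3 was uneven over the arms. It was 0.230% of H3K27me3 peaks on 2L, 0.251% on 2R and 0.247% on 3L, but 2.22% on 3R and 2.78% on X, where the H3K27me3 list was also denser, at 231 and 243 peaks per Mb against 151 to 165 on the others. When only the first 140 entries per Mb of each arm were kept, it was 0.154% on 3R and 0.159% on X. ASH2 was found at 34.4% of the H3K27me3 peaks on 2L, 31.3% on 3L and 26.0% on 2R, and at 21.9% on 3R and 18.8% on X. From the ASH2 side, 20.2% of ASH2 peaks overlapped H3K27me3 (arms 16.9 to 21.6, shifted 14.7%, ratio 1.37). This excess depended on ASH2 peak width: the observed share was 1.68 times the shifted share for the narrowest 30% of ASH2 peaks, 1.199 times for the wider 50% (21.5% against 17.9%), and for the 3732 widest ASH2 peaks it was a deficit, 16.7% against 23.0% shifted. With the H3K27me3 list alone kept to its 3732 widest peaks the excess stayed (7.16% against 5.75%), and among the first 50% of both lists' entries it shrank to 11.5% against 10.5%.

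Joining H3K27me3 peaks over gaps of up to 5000 bp gave 3800 domains with a median length of 1684 bp, of which 389 were longer than 20 kb, and together they covered 31.5 Mb. Domains held 7.08% of H3K36me3 peaks (shifted 30.8%, ratio 0.230), 11.5% of H3K4me3 peaks (29.1%, 0.393), 16.4% of Ser2P peaks (29.0%, 0.565) and 18.9% of Ser5P peaks (28.9%, 0.653). They held 32.1% of ASH2 peaks (27.3%, 1.18), and all 5 shares had an adjusted p of 0.0002. The longest domain, on 3R from 6253738 to 6521660 (267923 bp), contained 147 ASH2 peaks over 16.2% of its length, with 4 H3K4me3 peaks, 12 Ser2P peaks and 12 Ser5P peaks. The second, on 2L from 14368772 to 14605179 (236408 bp), contained 159 ASH2 peaks over 19.7% of its length and 3 H3K4me3 peaks. The third, on 2L from 21762696 to 21980556 (217861 bp), contained 88 ASH2 peaks over 12.4%. The fourth, on 3L from 12530964 to 12724137 (193174 bp), had 101 ASH2 peaks over 17.7% and the most Ser2P peaks of these domains, 23. The fifth, on 2L from 11284982 to 11475930 (190949 bp), had 96 ASH2 peaks over 12.1%. None of these 5 domains contained an H3K36me3 peak. The widest single H3K27me3 peak, on 3R from 7187813 to 7204849 (17037 bp), held a Ser5P peak over 17.3% of its length and 2 ASH2 peaks over 3.1%. Those on 2R from 5864290 to 5874877 (10588 bp) and from 20710385 to 20719502 (9118 bp) held no peak of any other target.

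**Figure D3:**
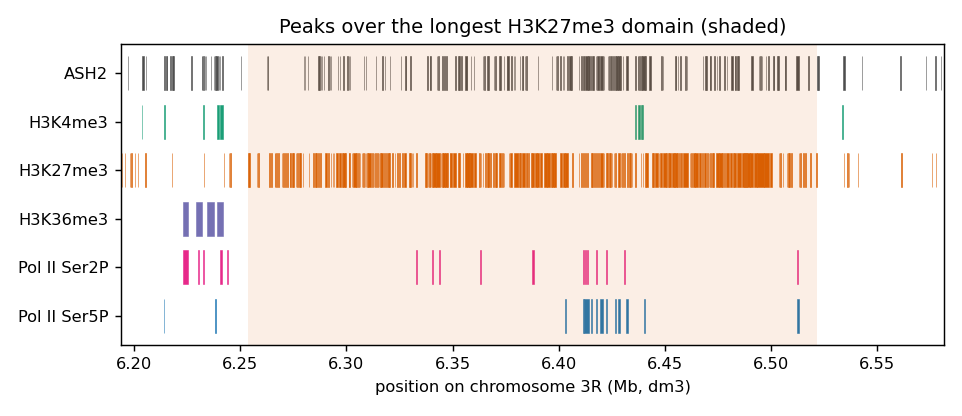
Peaks of the 6 targets (vertical axis) along the longest H3K27me3 domain, shaded, on 3R in dm3 (horizontal axis, position in Mb), each bar being a peak drawn to scale with a thin outline. The domain holds 147 ASH2 peaks and no H3K36me3 peak, with 4 H3K4me3 peaks.

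The last comparison between targets set the polymerase forms against each other. Ser5P peaks more often held ASH2 and H3K4me3, and Ser2P peaks more often held H3K36me3. ASH2 was present at 87.7% of Ser5P and 48.1% of Ser2P peaks, a difference of 39.6 percentage points (95% interval 37.8 to 41.3, odds ratio 7.67), and H3K4me3 at 57.9 and 39.7% (18.2 points, 16.1 to 20.3, odds ratio 2.09). Both were higher at Ser5P on 5 of 5 arms. H3K36me3 was present at 23.8% of Ser5P and 50.4% of Ser2P peaks (-26.6 points, -28.6 to -24.7, odds ratio 0.307) and was lower at Ser5P on all 5 arms. Fisher's exact test, two-sided and adjusted over the 4 marks, gave p = 1.297e-62 for H3K4me3 and 2.522e-142 for H3K36me3. Regions with both forms (1624 Ser5P and 1706 Ser2P peaks) entered both groups, which the test and the intervals treat as independent. H3K27me3 did not separate the forms in the whole lists (12.03 and 12.7%, -0.666 points, -2.07 to 0.738, adjusted exact p = 0.372), whereas the wider 50% of each list had more of it at Ser5P (2.93 points, adjusted exact p = 0.00115). Among the first 50% of entries the H3K4me3 difference was 2.05 points and no longer passed the exact test (adjusted p = 0.166).

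**Figure D4:**
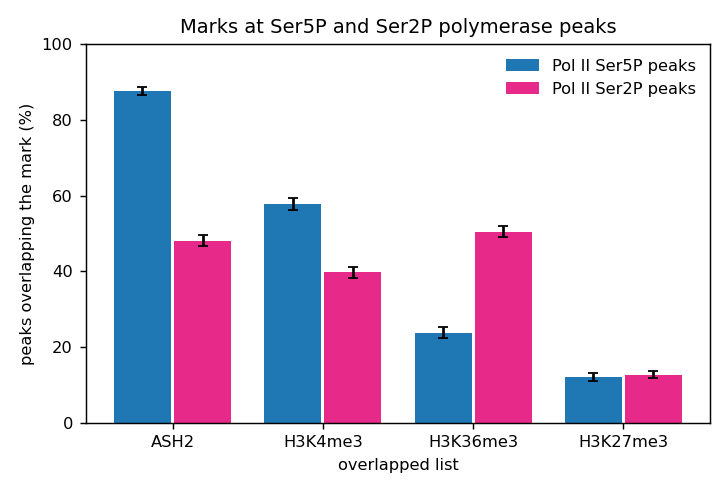
Percentage of Ser5P and Ser2P polymerase peaks (vertical axis) that overlapped ASH2, H3K4me3, H3K36me3 and H3K27me3 peaks (horizontal axis), with exact 95% intervals as error bars. ASH2 and H3K4me3 are higher at Ser5P peaks (87.7 against 48.1%, and 57.9 against 39.7%), and H3K36me3 is higher at Ser2P peaks (50.4 against 23.8%).

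The forms overlapped in part: 43.5% of Ser5P peaks met a Ser2P peak (arms 40.6 to 45.3, shifted 7.51%) and 35.3% of Ser2P peaks met a Ser5P peak (arms 33.0 to 39.3, shifted 5.80%). The 2108 Ser5P peaks without Ser2P rarely lay in H3K36me3 (8.59%, against 43.5% of the 1624 with Ser2P, odds ratio 8.21, adjusted exact p = 1.155e-139). After shifts, 10.9% of all Ser5P peaks lay in H3K36me3. More of the Ser5P peaks without Ser2P had ASH2 (90.6 against 83.9%), and fewer had H3K4me3 (52.0 against 65.4%). The 3122 Ser2P peaks without Ser5P had ASH2 at 30.5% and H3K4me3 at 27.1%, against 80.4 and 62.7% of the 1706 with Ser5P (odds ratios 9.33 and 4.51), and H3K36me3 at 53.8 against 44.2%. All Ser2P peaks after shifts gave 27.9% for ASH2, 8.40% for H3K4me3 and 11.3% for H3K36me3. Without Ser5P, ASH2 was thus close to that shifted share, and the other 2 marks were above theirs. The split groups were not shifted on their own. Fisher's exact test over these 8 comparisons gave adjusted p values up to 0.0256, apart from H3K27me3 at Ser2P peaks with and without Ser5P (12.4 and 12.8%, adjusted p = 0.684). Of the 5 widest Ser2P peaks, 4 lay almost wholly under H3K36me3: that on 2L from 6975868 to 6985214 (9347 bp) was covered over 96.9% by H3K36me3, and those on X from 6138010 to 6145961 (7952 bp) and from 18765668 to 18773403 (7736 bp) entirely so, and that on X from 10359470 to 10366306 (6837 bp) over 98.9%, all without ASH2, H3K4me3 or Ser5P. The fifth, on 3L from 8466975 to 8473776 (6802 bp), was covered over 68.4% by H3K36me3, over 68.3% by Ser5P and over 25.1% by H3K27me3. The widest Ser5P peak, on X from 3057449 to 3065101 (7653 bp), was covered over 96.0% by Ser2P and over 30.2% by H3K27me3, with no H3K36me3. The next, on 3R from 10639898 to 10647106 (7209 bp), was covered over 51.2% by Ser2P and over 12.9% by H3K27me3. The third, on 3L from 2788415 to 2795093 (6679 bp), was covered over 99.3% by H3K36me3, and the fourth and the fifth, on X from 3745498 to 3751254 and on 3L from 8466115 to 8471620, over 99.97 and 100%. The widest H3K36me3 peak, on X from 20269089 to 20282849 (13761 bp), held no peak of another target, and of the next 4, those on 3R from 20062462 to 20073662, on X from 6135287 to 6146041 and on 2L from 6975420 to 6984923 were covered by Ser2P over 82.1, 73.9 and 95.3%. Neighbouring peaks are not independent, so these p values are smaller than independent regions would give.

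Peak density on the X chromosome, which carries dosage compensation in males, was set against the autosomal arms. The sex of the larvae did not enter this comparison, so the ratios are not a measure of dosage compensation. Ser2P and H3K36me3 peaks were sparser on the X, with ratios to the mean of the 4 autosomal arms of 0.751 ± 0.184 and 0.801 ± 0.147 (SD over arms). ASH2 had a ratio of 0.909 ± 0.0383, H3K4me3 of 0.905 ± 0.100 and Ser5P of 0.912 ± 0.160. H3K27me3 peaks were denser on the X, with a ratio of 1.40 ± 0.219, although 3R (231 per Mb) came close to the X (243 per Mb). The gap exceeded the SD of the arms for ASH2, H3K27me3, H3K36me3 and Ser2P, and not for H3K4me3 and Ser5P. No test was made, since each list has 1 X chromosome. Counted as the share of the arm covered by peaks, the ratios for Ser2P, H3K36me3 and H3K27me3 moved to 0.920, 0.992 and 1.10.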

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

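Recomputing 57 results under 385 alternatives left 366 the same, while 12 reversed, 2 kept their direction and no longer passed the test, and 5 untested values moved. The same meant the same direction and side of the threshold, a value within the spread or, for counts of pairs, a count near the main one. Thus 10 pairs below shifts among the 3732 widest peaks of each list, against 8 in the main setting, counted as the same. Chosen after seeing the data were the alternatives by list order, the 20 to 100 kb shifts, the 100 bp minimum and the polymerase width window. So were the 140 entries per Mb and the cut of a single list to its widest peaks. The lower overlap of H3K27me3 with the 4 active marks than after shifts held in both directions of overlap and under every alternative run. Only Ser2P peaks at 50% overlap (7.705% against 8.796% shifted, adjusted p = 0.0765 by permutation) no longer passed the test. The ratio of H3K27me3 with H3K36me3 ran from 0.00682 for the first 50% of entries to 0.191 at 50% overlap. Among the 3732 widest peaks of each list, 5.734% of ASH2 peaks overlapped H3K27me3 (shifted 7.266%) and 5.654% of H3K27me3 peaks overlapped ASH2 (7.693%), reversing both excesses. In the same setting ASH2 was at 48.39% of H3K4me3 and 48.1% of Ser5P peaks, and among the first 50% of entries at 56.22% of H3K4me3 peaks, all above shifts. Cutting the ASH2 list alone to its 3732 widest peaks reversed them too (16.75%, shifted 23.02%, and 3.223%, shifted 4.786%), and cutting the H3K27me3 list alone did not (7.162%, shifted 5.748%, and 43.19%, shifted 34.52%). Among the first 50% of entries of both lists these excesses shrank to 11.47% (shifted 10.46%) and 15.67% (shifted 14.46%). The excess of ASH2 peaks at H3K36me3 reversed at 50% overlap (7.374%, shifted 7.436%, adjusted p = 0.757 by permutation) and for the first 50% of entries (4.965%, shifted 5.903%). The width difference of ASH2 peaks with H3K27me3 was -29 bp at 50% overlap, and by place in the list, on a scale from 1 to 1000, ASH2 peaks with H3K27me3 lay 119 places later and those with H3K36me3 139.5 places later than the rest. The Ser5P minus Ser2P difference with H3K27me3 changed sign to 1.354 points within 500 bp, 2.925 points in the wider 50% and 1.666 points in the first 50% of entries, and that with H3K4me3 was 2.054 points in the first 50%. Ratios of the X to the autosomes moved to 1.101 (covered length) and 1.126 (wider 50%) for H3K27me3, 0.9919 and 0.9749 for H3K36me3, and 1.01 (wider 50%) for H3K4me3. The cause was not tested for the others. Not run were the alternative restricted to euchromatic arms, which changes nothing in lists holding only such arms, width in place of score, which is already the measure, and the alternatives for genes, which need an annotation of dm3. No paired analysis was possible because each target has 1 library. Depth is unknown for every list.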

Other observations

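The width of an H3K4me3 peak went with how much transcription-linked chromatin overlapped it. In the narrowest 10% of H3K4me3 peaks (up to 411 bp) 1.87% overlapped H3K36me3 and 4.60% Ser2P, and in the widest 10% (1362 to 4654 bp) 72.4% and 63.8% did so. Ser5P rose less, from 23.9 to 54.9%. ASH2 hardly followed this order: it was present at 82.6% of the narrowest and 89.1% of the widest, and between 83.6 and 88.9% of those in between. A wider peak has more chance of meeting another list, and these shares were not set against shifts by width.

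H3K4me3 and H3K27me3 met at 469 H3K4me3 peaks, 7.99% of them, with 4.14 to 4.81% on 2L, 2R and 3L, 12.04% on 3R and 14.0% on X. With only the first 140 H3K27me3 entries per Mb the share was 3.715%. Along the H3K27me3 list, 3.71% of the first 10% of entries met H3K4me3, 0.531% of the entries from 40 to 50% and 5.84% of the last 10%. The 469 peaks had less H3K36me3 than the other 5399 (36.03 against 46.7%, odds ratio 0.644, two-sided Fisher's exact test, adjusted p = 3.37e-05), while Ser5P (38.8 against 37.1%, adjusted p = 0.606) and ASH2 (82.1 against 85.7%, adjusted p = 0.0686) did not pass the exact test. In the named positions, 3 of the 5 widest H3K4me3 peaks lay largely under H3K27me3: on 2R from 15714159 to 15718812 (51.2% covered), on 2R from 15999062 to 16003691 (76.3%) and on 3L from 15228907 to 15233309 (93.8%). They were covered by Ser5P over 96.9, 100 and 97.6% of their length and held no H3K36me3. In a disc made of several cell types, a shared position does not show that both marks lie in the same cells. The widest 10% of H3K4me3 peaks as a whole still met H3K27me3 less often than shifted peaks (12.3 against 28.8%, ratio 0.427).

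Below, tests chosen after the result was seen were that with active-mark peaks left out, those on wider and widest ASH2 peaks, that at matched places of the H3K27me3 list, those on places off the other ASH2 peaks and that on the share of narrow peaks near wider ones; the limit of 140 entries per Mb was picked after the densities and the trend along the list were known, with the tested share unseen.

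ASH2 peaks lay in H3K27me3 peaks more often than shifted peaks did, by a ratio of 1.37. A likeness of density over regions broader than 2 to 10 kb, as the whole cause, was argued against by shifts of that size, which left a ratio of 1.125. The shifted share rose from 14.73% along whole chromosomes to 16.63% with shifts of 20 to 100 kb (ratio 1.22). With 2 to 10 kb it was 17.97%, against 20.22% observed, so a large part of the excess may be regional. H3K27me3 domains had a median length of 1684 bp, below these shifts, so shared density at that finer scale is not excluded. Regions called with every antibody, as the whole cause, were argued against by leaving out all peaks with an active mark (1.871). The removal itself raises this value, because both lists then lack the same regions. Without removal, ASH2 peaks with H3K27me3 and no active mark stood at 1.31. Nonspecific regions called only in the ASH2 and H3K27me3 lists would pass this test, so they stay open. Narrow ASH2 calls as the whole cause were argued against by the wider 50% of ASH2 peaks (1.199). Among the first 50% of both lists' entries, however, the excess was slight (11.47% against 10.46% shifted). The first 140 H3K27me3 entries per Mb alone kept it (17.51% against 12.31%), but that cut leaves more of the H3K27me3 list than its first 50%. The ASH2 list was not cut alone by order, so late, possibly weak calls in either list stay open as a source. The ratio fell with ASH2 width all the same, and the 3732 widest ASH2 peaks met H3K27me3 less often than shifted peaks (16.75% against 23.02%). Input signal and what the ASH2 antibody bound were not tested and stay open, so ASH2 in Polycomb chromatin remains a hypothesis.

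H3K27me3 peaks with H3K36me3 lay late in the list and mostly on 3R and X. One candidate explanation is that the list is ordered by strength and runs into weaker calls on these arms. The last 10% of its entries had another H3K27me3 peak within 1 kb in 41.15% of cases, against 99.4% in the first, and overlapped H3K36me3 in 6.77% against 0.133%. The neighbour test goes with an order by strength, but median width also fell, from 1372 bp in the first 10% to 191 bp in the last. An order by width might pass the test too, so it cannot single out strength. A deeper list on 3R and X cannot be told apart from a difference of these arms. The low share in their first 140 entries per Mb (at most 0.1592%) restates that the overlaps lie late. Entries from 140 to 150 per Mb differed by 0.01418 points between 3R with X and the other arms (3 of 503 against 4 of 687, 95% interval -0.867 to 0.895). The later entries gave 5.404% on 3R, 6.34% on X, 0.752% on 2L (2 of 266), 0.452% on 2R (1 of 221) and 0.162% on 3L (1 of 619), but on the latter 3 arms the list ends at 151 to 165 entries per Mb, so most of the later places on 3R and X have no counterpart there.

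Narrow ASH2 peaks rarely met active marks: the narrowest 30% (9474 peaks of up to 104 bp) overlapped H3K4me3 at 0.632 and Ser5P at 0.659 times the shifted share. That low share may come from the other ASH2 peaks, which already occupy these places: against random places off those peaks the ratio was 1.208 for H3K4me3 and 1.33 for Ser5P, though still 0.784 for H3K36me3 and 0.490 for Ser2P. In the same test the ratio for H3K27me3 was 1.729 (1.68 against shifts), which argued against background spread evenly over the genome, while background that follows chromatin or sequence stays open and the input was not analysed here; an earlier test of background by the ratio to shifts at Ser5P decides nothing. Splitting from peaks of the wider 50% of the list, within 500 bp, could account for some of them but not for most. Pieces beside other ASH2 peaks, or farther away than 500 bp, were not counted, so splitting of those kinds stays open. Of these narrow peaks, 20.99% lay within 500 bp of the wider 50% of the list, 1.14 times the shifted share. Shifted peaks can land on those wider peaks, which real ones cannot, so the ratio of 1.14 is likely too low. No biological explanation was tested.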
